A study of Mus musculus with 36 samples.

How the data were processed

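RNA from 36 mouse cell preparations, 3 for each of 12 groups, was labelled with Cy3 from 0.5 µg of total RNA and hybridized to 1-colour Agilent arrays of design 014868, per the labels' protocols. All cells but the sorted monocytes were cultured for 7 days in all, with the stimulus in the last 24 h, per the labels. LPS is given there as 100 µg/ml, which is high for macrophage cultures; the unit was not checked here. Spots were read with Agilent Feature Extraction 10.5.1.1, protocol GE1_105_Jan09, and the intensity of each spot was background-corrected and processed by that program, per the file headers. The flags that mark a spot as well above background, uneven or an outlier were set by the same program, per the file headers. The series table held log2 intensities that the authors had quantile-normalized, and it correlated with the processed intensities at 0.997 or more on every array. Probe coordinates and build (mm8, NCBI36) were taken as deposited.

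The arrays lay 4 to a slide on 9 slides, scanned on 2 days. The labels number the series 1 to 3; each number covered 3 slides, one with monocytes, M0, M1 and M2a, one with M2b, M2c, IFN-γ macrophages and Mo-DC, and one with the 4 Mreg groups. Of 41174 probes, 24375 were named by accession and 8727 by symbol in a table of mouse genes (GRCm38.p6, used for names only); 8072 kept the name in the file. No spot was saturated, and no pair of arrays was identical. The 75th percentile of processed signal ran from 320.0 to 648 across arrays.

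Values were log2 of the processed signal minus the 75th percentile of the array. Uneven and outlying spots were set to missing, repeated spots were averaged, probes well above background on at least 3 of 36 arrays were kept (26478), and the brightest probe stood for each gene (17605 genes). limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 36 arrays, and contrasts were called at an adjusted p below 0.05 (Benjamini and Hochberg, within each comparison). Where a probe was not well above background on any array of one group, its values were raised to the lowest signal called well above background on the array, and the fold is given as at least the result. An adjusted p beside such a fold tests the fitted difference of the unraised values, not the bound. Where only some arrays of the dimmer group were above background, the fold is that of the means of all 3 arrays and rests partly on signal near background. Where both groups were below, no fold is given. Differences of responses were interaction contrasts, and their log2 values are given only for genes measured in all 4 groups. Genes set apart in Mreg had to pass against each of 8 other cell types in the same direction. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

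The 28 gene lists were written from general knowledge before the data were examined. They cover IFN-γ-induced genes, type I interferon-stimulated genes, MHC class II and class I presentation, nitric oxide and arginine metabolism, T cell costimulation and inhibition, proinflammatory cytokines and NF-κB targets, chemokines, IL-4-induced alternative activation, glucocorticoid-induced genes, Fc receptors and complement, cell cycle and proliferation, cholesterol synthesis, lipid efflux with LXR or PPAR targets, glycolysis and hypoxia, lysosome and phagocytosis, tissue remodelling, unfolded protein and oxidative stress, and markers of macrophages, Ly6C-high monocytes, neutrophils and granulocyte precursors, dendritic cells, T and NK cells, B and plasma cells, erythroid and megakaryocyte cells, mast cells with basophils and eosinophils, stromal and endothelial cells, and osteoclasts. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists within a comparison, and again with an estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone.

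The rule for named genes was also set before the data were examined. Per comparison it takes the 5 largest rises and 5 largest falls among calls whose groups did not overlap (ranked by fitted log2, also where signal lay below background), up to 3 members of each list with at least a 2-fold change, and always Nos2, Arg1, Ido1, Cd274, Il10, Tnf, Il12b, Cxcl9, Retnla and Mrc1; clone and predicted names were skipped. A few genes that the rule takes are not reported here. The alternatives were normexp background correction (offset 50) of mean signals, quantile normalization, no filter on dim probes, a filter of 18 arrays, the mean of all probes of a gene, the authors' series table, the series number as a block, the slide as a random block, only the compared groups in the fit, and each array left out in turn. One more, the arrays of a single scan day, was chosen after seeing the data.

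Pairing by series number was checked through the correlation of deviations from the group means. Every pair exceeded 0.1 in the IFN-γ, LPS, IL-4, dexamethasone and immunoglobulin comparisons (for IFN-γ in Mreg 0.340, 0.563 and 0.403), where shared slides or a shared series link the arrays. The slide correlation estimated for the random block was 0.229. The scripts were tested on simulated data with 200 genes changed. For IFN-γ in Mreg they recovered 22% of genes changed by log2 0.5, 66% at 1, 94% at 2 and 96% at 3, with 10 false calls, and for the difference of IFN-γ responses 10, 44, 80 and 88%, with 4 false calls. Control spots were left out, and the remaining columns of the array files were not used here.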

Results

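Transcript levels were measured in 12 groups of mouse myeloid cells, each on 3 single-colour arrays, 36 in all. Ly6C-positive bone marrow monocytes were the starting cells. From them came regulatory macrophages (Mreg), kept in 5 ng/ml M-CSF with human AB serum and given IFN-γ on the last day. Macrophages kept in 20 ng/ml M-CSF were left alone (M0) or given IFN-γ, IFN-γ with LPS (M1), IL-4 (M2a), IFN-γ on an immunoglobulin coating (M2b) or dexamethasone (M2c). Monocyte-derived dendritic cells (Mo-DC) were grown in GM-CSF and IL-4 and also given IFN-γ. Variants of the Mreg culture lacked IFN-γ, had LPS added, or began from adherent mononuclear cells that had not been sorted. Between 50.1 and 57.6% of the probes on an array were well above background, and 17605 genes were tested. All p-values measure only the spread between these arrays, because nothing in the labels says that the 3 arrays of a group came from separate animals.

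**Figure D1:**
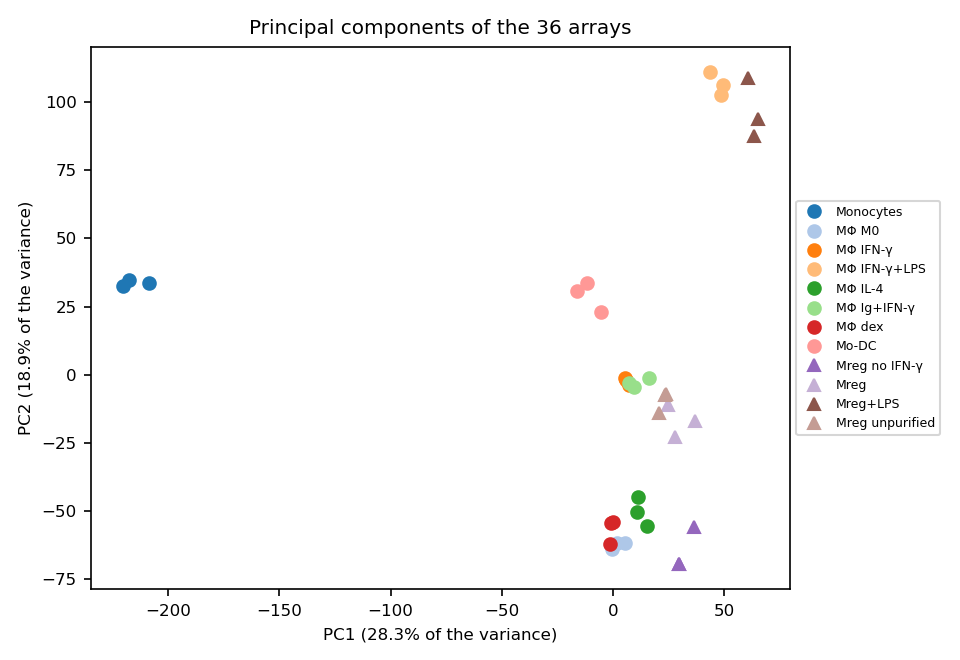
All 36 arrays on the first and second principal components of log2 signal, which held 28.3 and 18.9% of the variance; colours mark the 12 groups. The 3 arrays of each group lie near one another.

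The first question was how much of Nos2, which encodes the inducible nitric oxide synthase that turns arginine into nitric oxide, Mreg carried. On the log2 scale relative to each array's 75th percentile, its only probe read −5.43 ± 0.50 SD (n = 3) in Mreg and was well above background on 1 of the 3 arrays. Without IFN-γ it was above background on none of the arrays. M1 macrophages (2.86 ± 0.45 SD, n = 3), Mreg given LPS (1.99 ± 0.37 SD, n = 3) and Mo-DC (0.19 ± 0.25 SD, n = 3) carried it on all arrays. In Mreg the rise with IFN-γ was at least 1.19-fold (adjusted p = 6.0e-04), with a log2 change of −0.27 under normexp background correction. Arg1, whose arginase splits the same amino acid into ornithine and urea, read 5.54 ± 0.78 SD in Mreg against −1.86 ± 0.37 SD in IFN-γ macrophages (n = 3 each). It was above background on no monocyte array. The Nos2 probe lay at chromosome 11, 78775853 to 78775912 of build mm8. A single probe measured each gene here, so no second probe could be set beside it.

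**Figure D2:**
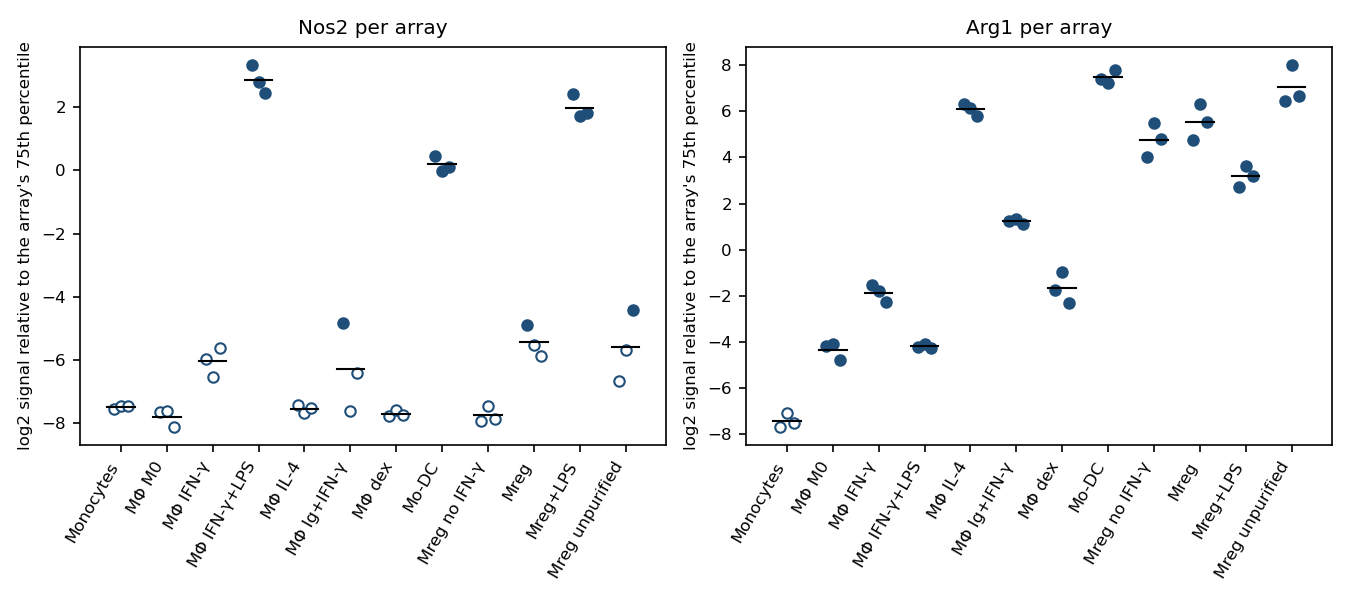
Log2 signal of Nos2 and Arg1, relative to the 75th percentile of each array, for every array of the 12 groups; filled points are well above background and bars are means. Nos2 stands high with LPS and in Mo-DC, and Arg1 in Mreg, M2a and Mo-DC.

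What IFN-γ does to Mreg was asked on slides that carried both groups, 3 arrays each. limma called 3596 genes, 1673 higher and 1923 lower, of which 845 and 590 changed at least 2-fold. Of these calls, 99.5% had the same direction on all 3 slides. Here and below, that share is taken among genes called from the same arrays, so a high value follows from the selection. The same holds for counts of calls whose arrays did not overlap. Rises included those of Iigp1, a GTPase that attacks the vacuoles of intracellular parasites (at least 6509-fold), the guanylate-binding protein gene Gbp4 (at least 374-fold), the class II transactivator Ciita (at least 381-fold), and the serine protease inhibitors Serpina3f (1448-fold with 1 of the 3 dimmer arrays above background) and Serpina3g (1269-fold with 2 of the 3 dimmer arrays above background). Gbp2, a GTPase of cell-autonomous defence, rose 1232-fold (log2 10.27 ± 0.21 SE, adjusted p = 9.2e-23), and Irf1, the transcription factor that spreads the interferon signal, rose 31.7-fold (log2 4.98 ± 0.13 SE, adjusted p = 2.7e-20). Of the IFN-γ-induced genes, 27 of 28 measured members rose (27 adjusted over the list alone, median log2 5.50, 5.09 at bounds, adjusted p = 1.8e-64, and adjusted p = 1.4e-04 with an estimated correlation). Genes of peptide supply to MHC class I followed: Tap1, the peptide pump, rose 9.67-fold (log2 3.27 ± 0.16 SE, adjusted p = 1.9e-14), Tapbpl, a peptide editor, 10.4-fold and the immunoproteasome subunit Psmb10 4.50-fold. In that list 15 of 15 measured members rose (15 adjusted over the list alone, median log2 1.71, adjusted p = 4.2e-33, and adjusted p = 4.4e-04 with an estimated correlation). H2-Ab1, a chain of the class II molecule that shows peptides to CD4 T cells, rose 125-fold (log2 6.96 ± 0.51 SE, adjusted p = 6.5e-11). Of the class II list 8 of 12 measured members rose (9 adjusted over the list alone, median log2 2.5, adjusted p = 3.7e-14, and adjusted p = 0.060 with an estimated correlation).

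Cd274, the PD-L1 ligand, rose 6.18-fold (log2 2.63 ± 0.18 SE, adjusted p = 1.6e-11) in the same cultures, and Entpd1, which strips phosphates from extracellular ATP, rose 4.90-fold. In the T cell costimulation and inhibition list 10 of 24 measured members rose and 4 fell (12 and 4 adjusted over the list alone, median log2 0.66, 0.47 at bounds, adjusted p = 6.6e-05, and adjusted p = 0.11 with an estimated correlation). DNA replication genes rose too, with the helicase subunits Mcm7 (3.53-fold) and Mcm5 (3.92-fold) among them. For the cell cycle list 27 of 30 measured members rose (27 adjusted over the list alone, median log2 1.54, adjusted p = 1.1e-19, and adjusted p = 0.11 with an estimated correlation). Ly6c1, a monocyte surface protein, rose 328-fold (log2 8.36 ± 0.55 SE, adjusted p = 8.8e-12), and Clec9a, a receptor for dead cells on cross-presenting dendritic cells, at least 74.1-fold. Falls were seen for the glutathione transferases Gsta1 (18.1-fold, log2 −4.18 ± 0.57 SE, adjusted p = 4.1e-06) and Gsta3 (12.8-fold), Galnt9, a mucin glycosyltransferase (18-fold with 2 of the 3 dimmer arrays above background), the myeloid receptor Trem3 (13.6-fold with 2 of the 3 dimmer arrays above background), and S1pr1, which guides cells out of tissue along sphingosine phosphate (13.1-fold). The reductases Txnrd1 (2.30-fold) and Nqo1 (3.50-fold), NRF2 targets, fell with their list, in which 11 of 25 measured members fell (11 adjusted over the list alone, median log2 −0.30, adjusted p = 3.8e-04, and adjusted p = 0.098 with an estimated correlation). Mrc1, the mannose receptor, fell 3.73-fold (adjusted p = 0.014), Tnf rose 2.72-fold (adjusted p = 0.0026) and the T cell chemoattractant Cxcl9 at least 13.9-fold. Il10 did not pass (log2 −0.26 ± 0.54 SE, adjusted p = 0.82), nor did Arg1 (log2 0.77 ± 0.40 SE, adjusted p = 0.20), which had an adjusted p = 0.024 with the slide as a fixed block. Il12b and Retnla were below background in both groups, and Ido1 was above background on 2 Mreg arrays only. The IL-4 list passed upward with a median log2 of −0.0017 and a mean log2 of 0.57 (adjusted p = 0.031, and adjusted p = 0.42 with an estimated correlation). In all, 13 of 28 lists passed, 2 of them with an estimated correlation. The count of genes fell to 2378 without the first Mreg array, to 2236 with normexp and to 2371 with only these groups in the fit. It was 1987 on a single scan day, a setting chosen after seeing the data.

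The same cytokine was then tested in M-CSF macrophages, with 3 arrays per group on different slides. 3907 genes were called, 1945 higher and 1962 lower, and in 3874 of them the arrays of the 2 groups did not overlap. Serpina3g (7816-fold with 1 of the 3 dimmer arrays above background), Gbp4 (at least 2041-fold), Gbp2b (at least 555-fold), Serpina3f (at least 918-fold) and Cxcl9 (at least 384-fold) rose. Gbp2 rose 304-fold (log2 8.25 ± 0.21 SE, adjusted p = 2.6e-20) and Irf1 11.5-fold (log2 3.52 ± 0.13 SE, adjusted p = 1.2e-16). Among the IFN-γ-induced genes 27 of 28 measured members rose (27 adjusted over the list alone, median log2 4.33, adjusted p = 5.0e-45, and adjusted p = 0.0016 with an estimated correlation). Among those of MHC class I presentation 15 of 15 measured members rose (15 adjusted over the list alone, median log2 1.48, adjusted p = 1.1e-23, and adjusted p = 0.0034 with an estimated correlation). Cd274 rose 11.3-fold (log2 3.50 ± 0.18 SE, adjusted p = 5.8e-14), Tnfrsf14, a ligand of the inhibitory receptor BTLA, 7.50-fold, and Arg1 5.62-fold (log2 2.49 ± 0.40 SE, adjusted p = 2.8e-05). For the T cell costimulation and inhibition list 12 of 24 measured members rose and 3 fell (12 and 3 adjusted over the list alone, median log2 1.23, 0.35 at bounds, adjusted p = 7.3e-05, and adjusted p = 0.14 with an estimated correlation). Ido1 rose at least 1.42-fold (adjusted p = 0.0071) but had a log2 change of −0.36 under normexp. Tnf rose 3.99-fold, Mrc1 fell 5.66-fold, and the cyclooxygenase Ptgs2, which makes prostaglandins, rose 110.0-fold with 1 of the 3 dimmer arrays above background. Sterol synthesis genes went down, with Fdft1 (2.34-fold, log2 −1.23 ± 0.13 SE, adjusted p = 4.2e-08) and Sqle (3.38-fold), consecutive enzymes of the squalene branch. In their list 2 of 24 measured members rose and 16 fell (3 and 16 adjusted over the list alone, median log2 −0.93, adjusted p = 4.5e-07, and adjusted p = 0.14 with an estimated correlation). The fatty acid carriers Fabp4 (28.7-fold) and Fabp5 (5.95-fold) fell with the LXR and PPAR targets, of which 1 of 24 measured members rose and 11 fell (2 and 11 adjusted over the list alone, median log2 −0.58, −0.49 at bounds, adjusted p = 5.9e-04, and adjusted p = 0.14 with an estimated correlation). Gas6, the bridge between dying cells and their phagocytic receptors, fell 9.08-fold, and the collagenolytic cathepsin Ctsk 10.9-fold. In the lysosome and phagocytosis list 2 of 30 measured members rose and 14 fell (2 and 14 adjusted over the list alone, median log2 −0.26, adjusted p = 4.5e-04, and adjusted p = 0.48 with an estimated correlation). Falls also included the serotonin receptor Htr2b (at least 30.9-fold), Galnt9 (at least 19.6-fold), the matrix protein gene Mamdc2 (50.2-fold), the small GTPase Rhoj (46.7-fold with 1 of the 3 dimmer arrays above background) and the G protein brake Rgs16 (at least 33.7-fold). Nos2, Il12b and Retnla were below background in both groups, and Il10 did not pass (log2 0.20 ± 0.54 SE, adjusted p = 0.88). The groups shared no slide, so a slide effect could enter; with the slide as a random block the count was 3913.

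The difference of the cultures' IFN-γ responses was tested next. Across genes, which are not independent replicates, the responses correlated at r = 0.741 (Spearman 0.618), and of 2178 genes called in both, 99.7% had the same direction. The difference itself passed for 290 genes, 209 with a more positive response in Mreg and 81 with a more negative one. It passed for 470 with the replicate number as a block, for 567 with only the compared groups in the fit, for 180 without the filter on dim probes and for 38 with normexp. On a single scan day, a setting chosen after seeing the data, it passed for 71, 47.9% of them more positive against 72.1%. Irf1 (log2 1.47 ± 0.19 SE, adjusted p = 5.3e-05) and the T cell-specific GTPase gene Tgtp1 (log2 4.12 ± 0.52 SE, adjusted p = 4.7e-05) responded more in Mreg, as did Cx3cl1, a membrane-bound chemokine (log2 5.15 ± 0.71 SE, adjusted p = 1.5e-04), Ly6a, the Sca-1 antigen (log2 4.68 ± 0.86 SE, adjusted p = 0.0046), and Ly6c1 (log2 4.41 ± 0.78 SE, adjusted p = 0.0033). The responses of Mcm5 (log2 1.95 ± 0.34 SE, adjusted p = 0.0033) and Mcm7 (log2 1.62 ± 0.31 SE, adjusted p = 0.0068) differed likewise. In the cell cycle list 10 of 30 measured members passed, 25 adjusted over the list alone (median log2 1.45, adjusted p = 2.2e-32, and adjusted p = 0.074 with an estimated correlation). Insig1, which restrains cholesterol synthesis, differed by log2 1.40 ± 0.30 SE, adjusted p = 0.014; 8 of the 24 sterol genes passed, 13 adjusted over the list alone (median log2 0.87, adjusted p = 2.5e-15, and adjusted p = 0.064 with an estimated correlation). For the type I interferon list 3 of 23 passed, 11 adjusted over the list alone (median log2 1.31, adjusted p = 7.1e-14, and adjusted p = 0.26 with an estimated correlation). Negative differences included Ddx4, a germ-line RNA helicase (log2 −3.43 ± 0.49 SE, adjusted p = 2.8e-04), Vegfa, the vessel growth factor (log2 −1.39 ± 0.28 SE, adjusted p = 0.0091), and the death receptor Fas (log2 −1.06 ± 0.25 SE, adjusted p = 0.028). Cd274 (log2 −0.87 ± 0.25 SE, adjusted p = 0.082), Il10 (log2 −0.46 ± 0.77 SE, adjusted p = 0.93), Tnf (log2 −0.56 ± 0.48 SE, adjusted p = 0.79) and Mrc1 (log2 0.60 ± 0.78 SE, adjusted p = 0.89) did not pass. Arg1 did not pass either (log2 −1.72 ± 0.56 SE, adjusted p = 0.14), with an adjusted p = 0.045 under the block. Cxcl9 passed (adjusted p = 0.026) but was below background in 2 of the 4 groups, and Nos2, Ido1, Il12b and Retnla, below background in at least 2, did not pass. Taking out single arrays moved the count to 144, 132 or 173 (IFN-γ macrophages 1, 2 and 3), 143, 184 or 124 (M0 1, 2 and 3), 177 or 193 (Mreg 1 and 3) and 175 or 160 (Mreg without IFN-γ 1 and 2).

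**Figure D3:**
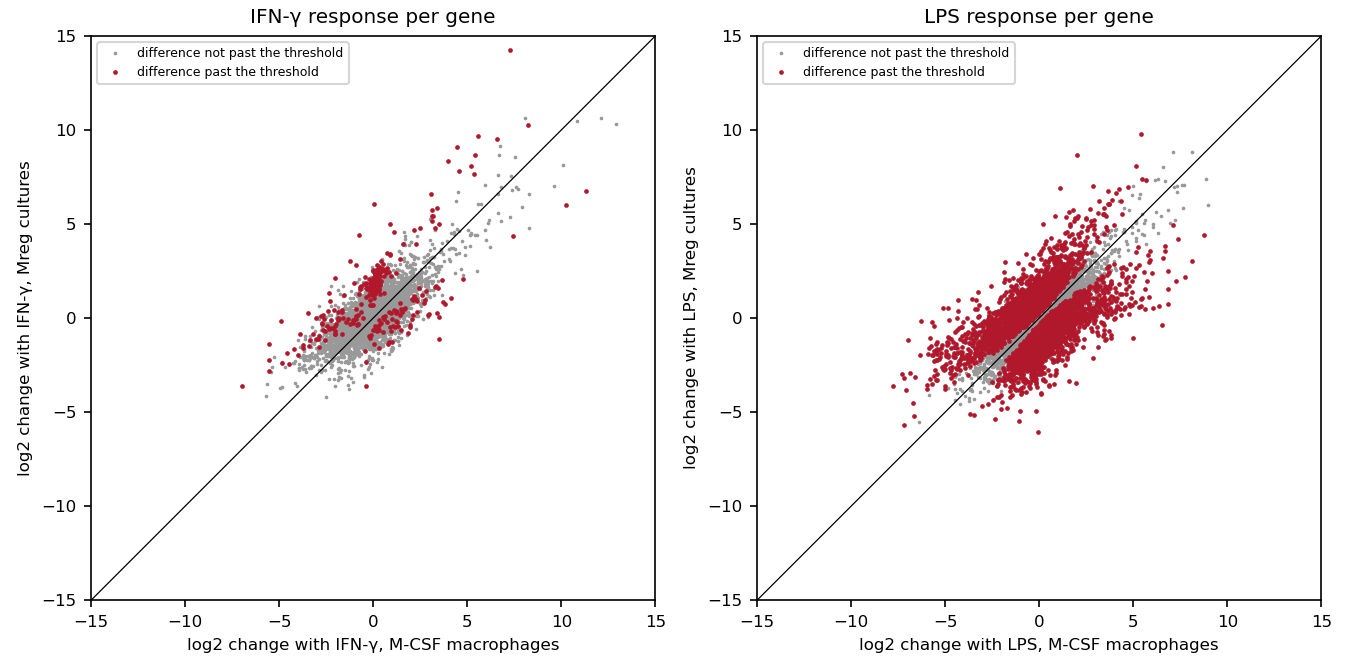
Log2 response to IFN-γ and to LPS in Mreg (vertical) and M-CSF macrophages (horizontal), 1 point per gene; red points passed the test of the difference. The IFN-γ responses lie nearer the diagonal than the LPS responses.

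How the culture itself shapes IFN-γ-treated cells was asked by setting Mreg against IFN-γ macrophages, on different slides. 4929 genes differed, 2463 higher and 2466 lower in Mreg, 1018 and 751 of them at least 2-fold, and 4830 without overlap of the arrays. Sdc1, a heparan sulfate carrier of plasma cells and macrophages, was 231-fold (log2 7.85 ± 0.53 SE, adjusted p = 4.9e-11) higher, Arg1 169.6-fold (log2 7.41 ± 0.40 SE, adjusted p = 1.4e-12) and Cav1, the coat protein of caveolae, 137-fold (log2 7.10 ± 0.49 SE, adjusted p = 7.0e-11). The elongation factor Eef1a2 (at least 41.4-fold) and the eosinophil-type ribonuclease Ear1 (at least 42.4-fold) were also higher. Plac8, a monocyte gene, was 284-fold (log2 −8.15 ± 0.56 SE, adjusted p = 5.6e-11) lower, as were the oxysterol enzyme Ch25h (59.6-fold with 2 of the 3 dimmer arrays above background), Ms4a3 of granulocyte-monocyte progenitors (at least 8.78-fold), the fatty acid receptor Gpr84 (at least 15.5-fold) and the chemokine Cxcl10 (36.1-fold). Inflammatory genes were lower in Mreg, with Cxcl9 at 28-fold (log2 −4.81 ± 0.70 SE, adjusted p = 7.2e-06), Tnf at 5.60-fold (log2 −2.49 ± 0.34 SE, adjusted p = 3.0e-06) and the costimulatory receptor Cd40 at 3.30-fold. In the NF-κB list 2 of 27 measured members were higher and 13 lower (2 and 14 adjusted over the list alone, median log2 −0.91, −0.35 at bounds, adjusted p = 0.0014, and adjusted p = 0.35 with an estimated correlation). Among type I interferon-stimulated genes 21 of 23 measured members were lower (23 adjusted over the list alone, median log2 −1.94, adjusted p = 2.9e-13, and adjusted p = 0.35 with an estimated correlation); Dhx58, a regulator of RNA sensing, was 3.38-fold lower. Glucocorticoid-induced genes stood higher, such as Glul, which makes glutamine (13.3-fold, log2 3.73 ± 0.27 SE, adjusted p = 1.6e-10), the transcription factor Klf9 (13.3-fold) and the lipase inhibitor Angptl4 (15.2-fold). Of that list 11 of 25 measured members were higher and 3 lower (11 and 3 adjusted over the list alone, median log2 0.68, 0.42 at bounds, adjusted p = 6.2e-04, and adjusted p = 0.35 with an estimated correlation). The oxygen sensor Egln3 (114-fold with 1 of the 3 dimmer arrays above background) and the mitophagy receptor Bnip3 (2.97-fold) were higher. In the glycolysis and hypoxia list 15 of 28 measured members were higher and 1 lower (18 and 1 adjusted over the list alone, median log2 0.51, adjusted p = 1.9e-05, and adjusted p = 0.49 with an estimated correlation). The matrix metalloproteinase gene Mmp19 was 7.02-fold (log2 2.81 ± 0.33 SE, adjusted p = 3.5e-07) higher. Of the remodelling list 8 of 23 measured members were higher (8 adjusted over the list alone, median log2 0.48, adjusted p = 0.0069, and adjusted p = 0.49 with an estimated correlation). Cd274 (log2 0.29 ± 0.18 SE, adjusted p = 0.25), Il10 (log2 −0.93 ± 0.54 SE, adjusted p = 0.22) and Mrc1 (log2 −0.41 ± 0.55 SE, adjusted p = 0.64) did not pass. Neither did Nos2 (adjusted p = 0.38), above background on 1 Mreg array and 0 of the IFN-γ macrophage arrays, or Ido1 (adjusted p = 0.95), while Il12b and Retnla were below background in both groups. Serum, M-CSF dose and slide all differed between the groups and cannot be separated; the count was 4910 with the slide as a random block and 3175 with normexp.

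The cultures were next compared without IFN-γ, again on different slides. 5439 genes differed, 3026 higher and 2413 lower in Mreg culture, and in 5365 the arrays did not overlap. Arg1 was 560.3-fold (log2 9.13 ± 0.40 SE, adjusted p = 1.6e-14) higher, as were Ear10 (at least 41.6-fold), Eef1a2 (123-fold with 1 of the 3 dimmer arrays above background), Cav1 (97.7-fold, log2 6.61 ± 0.49 SE, adjusted p = 2.7e-10) and Ear1 (88.7-fold with 1 of the 3 dimmer arrays above background). Lower were Iigp1 (at least 70.1-fold), Ifi44, an interferon-stimulated antiviral gene (at least 165-fold), the junction protein gene Ctnnd2 (at least 25.9-fold) and complement factor Cfb (at least 52.8-fold). Zbp1, a sensor of viral nucleic acid, was 18.8-fold (log2 −4.23 ± 0.31 SE, adjusted p = 2.7e-10) lower, and Ifit1, which binds viral RNA, 25.8-fold. In the type I interferon list 23 of 23 measured members were lower (23 adjusted over the list alone, median log2 −3.19, adjusted p = 7.3e-25, and adjusted p = 0.084 with an estimated correlation). Division genes were lower, with Birc5, the survivin of the mitotic spindle, at 6.65-fold (log2 −2.73 ± 0.32 SE, adjusted p = 2.8e-07). For the cell cycle list 28 of 30 measured members were lower (28 adjusted over the list alone, median log2 −2.0, adjusted p = 7.6e-21, and adjusted p = 0.12 with an estimated correlation). Ccr2, the receptor that draws monocytes to CCL2, was 15.1-fold (log2 −3.91 ± 0.43 SE, adjusted p = 1.0e-07) lower and Ly6c1 43.6-fold. Among Ly6C-high monocyte markers 2 of 18 measured members were higher and 7 lower (2 and 7 adjusted over the list alone, median log2 −0.70, −0.56 at bounds, adjusted p = 0.0078, and adjusted p = 0.19 with an estimated correlation). Vegfa (4.52-fold) and Cd274 (2.25-fold, log2 1.17 ± 0.18 SE, adjusted p = 1.3e-05) were higher, and Tnf (3.81-fold) and the chemokine Ccl4 (8.56-fold) lower. Il10 (log2 −0.47 ± 0.54 SE, adjusted p = 0.57) and Mrc1 (log2 −1.01 ± 0.55 SE, adjusted p = 0.18) did not pass, and Nos2, Ido1, Il12b, Cxcl9 and Retnla were below background in both groups. A slide effect could enter here as well, and the random block gave 5437 genes, normexp 3095.

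A further set of tests asked which genes set Mreg apart from 8 other cell types at once. The 8 were monocytes, Mo-DC, M0, IFN-γ, M1, M2a, M2b and M2c macrophages. 157 genes were higher in Mreg than in every one of them (42 at least 2-fold each time) and 172 were lower (44 at least 2-fold). Against Mreg without IFN-γ, 103 of the 157 were not called, 27 were higher in Mreg and 27 lower; of the 172, 132 were not called, 36 were lower and 4 higher. Ranked after their values were seen, genes with large smallest-differences included Prl2c5, a proliferin-family hormone gene (12.7-fold over M2a, adjusted p = 6.5e-06), and Cavin3, a partner of Cav1 in caveolae (12-fold over Mo-DC, adjusted p = 5.9e-06). The lipid droplet coat gene Plin1 exceeded all 8 groups, each below background, by at least 5.65-fold. Notch4, a receptor of endothelial patterning (6.38-fold over M2c), Angptl4 (5.78-fold over M2a) and Col18a1, the source of endostatin (5.65-fold over M2c), followed. Lower in Mreg were Pilrb2 (6.32-fold, closest to M2a) and Pilra (6.00-fold, closest to M2c), paired receptors for glycoproteins, the sugar transporter gene Slc2a6 (6.06-fold), the macrophage growth factor Csf1 (4.75-fold, adjusted p = 2.2e-04) and the chemokine Ccl3 (3.75-fold under IFN-γ macrophages, adjusted p = 9.6e-04). Each of these was measured on all 3 Mreg arrays. Mreg shared no slide with the other 8 groups, and with normexp 92 genes were higher and 90 lower.

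**Figure D4:**
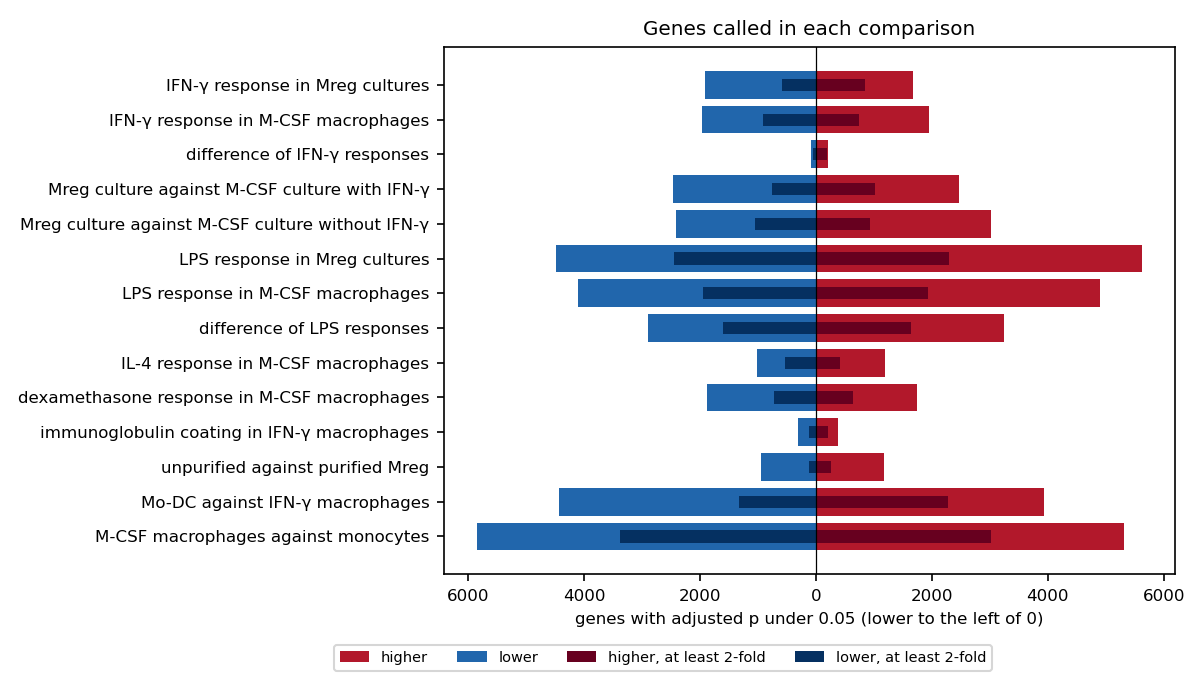
Genes past adjusted p 0.05 in each of 14 comparisons, higher to the right and lower to the left. LPS and the step from monocyte to macrophage changed the most genes, the difference of IFN-γ responses the fewest.

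What LPS adds to IFN-γ in Mreg was asked on shared slides. 10103 genes were called (5622 higher, 4481 lower), 2298 and 2449 at least 2-fold, and 98.9% had the same direction on all 3 slides. Ccl5, which attracts T cells and NK cells, rose 899.7-fold (log2 9.81 ± 0.75 SE, adjusted p = 1.8e-11), the red pulp macrophage factor Spic 463-fold (log2 8.85 ± 0.69 SE, adjusted p = 2.4e-11), the acute-phase protein gene Saa3 457-fold, the iron hormone Hamp at least 92.3-fold and complement C3 275-fold (log2 8.10 ± 0.41 SE, adjusted p = 9.5e-15). Nos2 rose 171-fold (log2 7.42 ± 0.47 SE, adjusted p = 5.3e-13, well above background on 1 of the 3 dimmer arrays), while Arg1 fell 5.13-fold (log2 −2.36 ± 0.40 SE, adjusted p = 1.3e-05). Il12b, a subunit of IL-12 and IL-23, rose at least 28.6-fold, Cxcl9 92.1-fold, Cd40 125-fold (log2 6.96 ± 0.28 SE, adjusted p = 2.3e-16), Cd274 4.46-fold (log2 2.16 ± 0.18 SE, adjusted p = 9.0e-11), Il10 2.66-fold (adjusted p = 0.029) and Tnf 3.08-fold. Traf1, an adaptor of the TNF receptors, rose 103-fold (log2 6.69 ± 0.25 SE, adjusted p = 6.2e-17) and Ptges, which completes prostaglandin E2, 49.9-fold. In the NF-κB list 26 of 27 measured members rose (26 adjusted over the list alone, median log2 3.31, 2.91 at bounds, adjusted p = 2.2e-11, and adjusted p = 0.030 with an estimated correlation). Isg15, a ubiquitin-like antiviral modifier, rose 26.8-fold (log2 4.74 ± 0.38 SE, adjusted p = 4.3e-11). Of the type I interferon list 23 of 23 measured members rose (23 adjusted over the list alone, median log2 4.04, adjusted p = 5.4e-11, and adjusted p = 0.59 with an estimated correlation). Replication genes went down, with Tk1, the thymidine kinase of S phase, at 13.7-fold (log2 −3.78 ± 0.32 SE, adjusted p = 1.1e-10). For the cell cycle list 2 of 30 measured members rose and 24 fell (2 and 25 adjusted over the list alone, median log2 −1.73, −1.65 at bounds, adjusted p = 5.5e-07, and adjusted p = 0.85 with an estimated correlation). Notch4 fell 45.3-fold (log2 −5.50 ± 0.49 SE, adjusted p = 3.5e-10), the organic anion carrier Slco2b1 66.9-fold with 1 of the 3 dimmer arrays above background, the lipid kinase Dgkg at least 10.8-fold, the cell cycle repressor E2f7 at least 10.1-fold and the growth factor brake Lrig1 at least 12.3-fold. Ido1 did not pass (adjusted p = 0.46) and was above background on 2 arrays of each group. Mrc1 did not pass (log2 −1.14 ± 0.55 SE, adjusted p = 0.079) but had an adjusted p = 0.047 with the replicate number as a block. Retnla was below background in both groups. The LPS arrays were dimmer, with 75th percentiles of 320.0 to 343 against 441 to 579. The median change of all genes was log2 0.17, so the scaling matters for small changes, and with quantile normalization 45.5% rather than 55.7% of calls were higher.

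LPS was also added to IFN-γ-treated M-CSF macrophages, compared across slides. 9013 genes were called (4904 higher, 4109 lower), and in 8817 the arrays did not overlap. Il1a, a cytokine released by dying cells, rose at least 255-fold, Nos2 at least 376-fold, Il6 435-fold with 2 of the 3 dimmer arrays above background, Spic 285-fold (log2 8.15 ± 0.69 SE, adjusted p = 1.6e-10) and the phospholipase Pla1a at least 70.6-fold. Tnf rose 13.7-fold (log2 3.77 ± 0.34 SE, adjusted p = 5.3e-10), Ido1 8.87-fold (log2 3.15 ± 0.75 SE, adjusted p = 8.7e-04), Cxcl9 30.6-fold, Cd274 4.35-fold and Il12b at least 50.6-fold. Arg1 fell 5.01-fold (log2 −2.33 ± 0.40 SE, adjusted p = 2.1e-05) and Mrc1 6.14-fold. Traf1 rose 157-fold (log2 7.30 ± 0.25 SE, adjusted p = 2.0e-17) and Irak3, a brake on Toll-like receptor signals, 11.5-fold. Of the NF-κB list 27 of 27 measured members rose (27 adjusted over the list alone, median log2 3.77, 3.44 at bounds, adjusted p = 2.2e-18, and adjusted p = 0.0025 with an estimated correlation). The chemokines Ccl3 (20.5-fold, log2 4.35 ± 0.42 SE, adjusted p = 1.8e-09) and Cxcl16 (16.5-fold) rose. In their list 15 of 21 measured members rose and 3 fell (15 and 3 adjusted over the list alone, median log2 2.99, 2.78 at bounds, adjusted p = 3.8e-04, and adjusted p = 0.23 with an estimated correlation). Txnrd1 (4.46-fold, log2 2.16 ± 0.12 SE, adjusted p = 7.0e-14) and Srxn1 (8.36-fold), which rescue oxidized thiols, rose, and 14 of 25 measured members rose and 4 fell (16 and 4 adjusted over the list alone) of the stress list (median log2 1.23, adjusted p = 2.8e-04, and adjusted p = 0.16 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 (at least 79.8-fold), the kinetochore protein gene Cenpf (at least 42.4-fold), cyclin Ccna2 (148-fold with 1 of the 3 dimmer arrays above background), Dgkg (at least 43.6-fold) and Pimreg (at least 30.9-fold) fell. In the cell cycle list 1 of 30 measured members rose and 27 fell (1 and 28 adjusted over the list alone, median log2 −3.94, −3.81 at bounds, adjusted p = 1.9e-22, and adjusted p = 0.16 with an estimated correlation). Il10 did not pass (log2 1.21 ± 0.54 SE, adjusted p = 0.066), though its adjusted p = 0.027 with the replicate number as a block, and Retnla was below background in both groups. M1 arrays were dimmer, with 75th percentiles of 413 to 436 against 541 to 589. The random slide block gave 8942 genes. Without the filter on dim probes 13875 were called, 70.7% of them higher against 54.4%.

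The LPS responses of both cultures were then tested against each other. Across genes, which are not independent replicates, they correlated at r = 0.640 (Spearman 0.583); 6432 genes were called in both, 88.2% of them in the same direction. The difference passed for 6153 genes, 3253 with a more positive response in Mreg and 2900 with a more negative one. With normexp it passed for 3872. More negative responses in Mreg were seen for Tnf (log2 −2.15 ± 0.48 SE, adjusted p = 8.5e-04), the monocyte attractants Ccl2 (log2 −4.05 ± 0.45 SE, adjusted p = 1.4e-07) and Ccl7 (log2 −5.02 ± 0.82 SE, adjusted p = 2.8e-05), and Tlr4, the LPS receptor itself (log2 −2.24 ± 0.28 SE, adjusted p = 7.6e-07). The proinflammatory list (adjusted p = 0.13) and the chemokine list (adjusted p = 0.28) did not pass. Nqo1 (log2 −3.66 ± 0.34 SE, adjusted p = 9.8e-09) and Txnrd1 (log2 −2.06 ± 0.17 SE, adjusted p = 1.4e-09) differed in the same direction, while their stress list did not pass (adjusted p = 0.28). Lpar1, a lysophosphatidic acid receptor, also had a more negative response (log2 −5.51 ± 0.68 SE, adjusted p = 5.9e-07). Positive differences were seen for Cd40 (log2 2.23 ± 0.40 SE, adjusted p = 8.0e-05), Vsir, the checkpoint protein VISTA (log2 2.96 ± 0.25 SE, adjusted p = 2.5e-09), the kinase Sgk1 (log2 3.91 ± 0.60 SE, adjusted p = 1.1e-05) and the oncogene Myc (log2 4.14 ± 0.37 SE, adjusted p = 5.6e-09). For the cell cycle list 25 of 30 measured members passed, as many adjusted over the list alone (median log2 2.11, adjusted p = 1.2e-12, and adjusted p = 0.98 with an estimated correlation). Oasl2, an antiviral protein gene (log2 2.27 ± 0.46 SE, adjusted p = 3.5e-04), and 14 others of the 23 type I interferon genes passed, 15 adjusted over the list alone (median log2 1.41, adjusted p = 6.6e-04, and adjusted p = 0.98 with an estimated correlation). H2-Aa, the partner chain of H2-Ab1, differed by log2 2.73 ± 0.75 SE, adjusted p = 0.0052, and 8 of 12 class II genes passed, 8 adjusted over the list alone (median log2 1.5, adjusted p = 0.020, and adjusted p = 0.98 with an estimated correlation). Arg1 (log2 −0.03 ± 0.56 SE, adjusted p = 0.97), Cd274 (log2 0.04 ± 0.25 SE, adjusted p = 0.93), Il10 (log2 0.20 ± 0.77 SE, adjusted p = 0.88), Cxcl9 (log2 1.59 ± 0.99 SE, adjusted p = 0.23) and Mrc1 (log2 1.48 ± 0.78 SE, adjusted p = 0.15) did not pass, nor did Ido1 (log2 −2.48 ± 1.05 SE, adjusted p = 0.070), with an adjusted p = 0.033 under the replicate block. Nos2 (adjusted p = 0.088), Il12b and Retnla, each below background in at least 1 of the 4 groups, did not pass. The Mreg response was read within slides and the other across slides, so slide effects could enter; a random slide block gave 6600 genes.

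The IL-4 response of M-CSF macrophages was read on shared slides. 2209 genes were called (1189 higher, 1020 lower), and 99.4% had the same direction on all 3 slides. Arg1 rose 1388-fold (log2 10.44 ± 0.40 SE, adjusted p = 5.5e-16), Retnla, a secreted marker of alternative activation, at least 917-fold, the chitinase-like genes Chil4 446-fold and Chil3 189-fold (log2 7.56 ± 1.26 SE, adjusted p = 1.4e-04), and the galactose lectin Mgl2 444-fold with 2 of the 3 dimmer arrays above background. Rnase2a, an eosinophil-type ribonuclease, rose 159-fold (log2 7.32 ± 0.35 SE, adjusted p = 4.7e-14). Of the IL-4 list 23 of 29 measured members rose (25 adjusted over the list alone, median log2 3.23, adjusted p = 1.8e-33, and adjusted p = 1.8e-05 with an estimated correlation). Slc7a2, which imports arginine, rose 40.7-fold (log2 5.35 ± 0.45 SE, adjusted p = 3.7e-09). In the arginine and nitric oxide list 6 of 14 measured members rose and 1 fell (6 and 1 adjusted over the list alone, median log2 0.31, 0.27 at bounds, adjusted p = 0.0012, and adjusted p = 0.084 with an estimated correlation). Cd274 rose 3.58-fold (log2 1.84 ± 0.18 SE, adjusted p = 6.3e-08), and Socs1, which silences JAK kinases, 11.8-fold (log2 3.56 ± 0.37 SE, adjusted p = 1.8e-07). Tk1 fell 6.91-fold (log2 −2.79 ± 0.32 SE, adjusted p = 8.0e-07) and Mcm7 3.35-fold. For the cell cycle list 28 of 30 measured members fell (29 adjusted over the list alone, median log2 −1.72, adjusted p = 2.5e-34, and adjusted p = 0.059 with an estimated correlation). Ocstamp, needed when osteoclasts fuse, rose 58.7-fold (log2 5.88 ± 0.46 SE, adjusted p = 1.1e-09). Among osteoclast markers 8 of 15 measured members rose and 1 fell (10 and 2 adjusted over the list alone, median log2 1.13, adjusted p = 2.0e-04, and adjusted p = 0.084 with an estimated correlation). Cx3cr1, the fractalkine receptor (at least 8.22-fold), Sncaip (18.4-fold with 1 of the 3 dimmer arrays above background), the formyl peptide receptors Fpr1 (16.4-fold, log2 −4.04 ± 0.77 SE, adjusted p = 6.1e-04) and Fpr2 (13.3-fold), and Cxcl10 (at least 8.30-fold) fell. Tnf did not pass (log2 −0.49 ± 0.34 SE, adjusted p = 0.41), and neither did Il10 (log2 −1.21 ± 0.54 SE, adjusted p = 0.16), which had an adjusted p = 0.012 with the slide as a fixed block. Mrc1 did not pass either (log2 1.42 ± 0.55 SE, adjusted p = 0.095), with an adjusted p = 0.048 under the replicate block. Nos2, Ido1, Il12b and Cxcl9 were below background in both groups. The count fell to 1309 without the first M2a array, to 1465 with only these groups in the fit and to 958 on a single scan day, which was chosen after seeing the data. With quantile normalization 43.6% rather than 53.8% of calls were higher.

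Dexamethasone was tested in M-CSF macrophages across slides. 3635 genes were called (1749 higher, 1886 lower), 3591 without overlap of the arrays. Jaml, an adhesion molecule of leukocyte passage, rose 618-fold (log2 9.27 ± 0.38 SE, adjusted p = 2.6e-15), Ms4a8a at least 74.9-fold, the matrix protease Adamts20 at least 133-fold, the homeobox gene Hoxd13 at least 51.0-fold and Mrap, an adaptor of the corticotropin receptor, 91.1-fold with 1 of the 3 dimmer arrays above background. The receptor co-chaperone Fkbp5 rose 52.8-fold (log2 5.72 ± 0.36 SE, adjusted p = 8.7e-12), the mTOR inhibitor Ddit4 44.4-fold (log2 5.47 ± 0.29 SE, adjusted p = 3.1e-13) and Tsc22d3, the glucocorticoid leucine zipper, 7.93-fold. Of the glucocorticoid-induced genes 17 of 25 measured members rose and 2 fell (18 and 2 adjusted over the list alone, median log2 2.10, 2.06 at bounds, adjusted p = 1.1e-11, and adjusted p = 0.0036 with an estimated correlation). Fcgrt, the neonatal Fc receptor that recycles IgG, rose 3.86-fold (log2 1.95 ± 0.30 SE, adjusted p = 2.5e-05). In the Fc receptor and complement list 8 of 24 measured members rose and 1 fell (9 and 1 adjusted over the list alone, median log2 0.69, adjusted p = 0.0071, and adjusted p = 0.46 with an estimated correlation). Tnf fell 5.49-fold (log2 −2.46 ± 0.34 SE, adjusted p = 6.3e-06), Cd274 1.80-fold (log2 −0.85 ± 0.18 SE, adjusted p = 0.0011), and Arg1 rose 6.42-fold (log2 2.68 ± 0.40 SE, adjusted p = 1.9e-05). The integrin Itgb3 rose 82.7-fold and haptoglobin Hp 41.9-fold. Slc2a1, the main glucose carrier (2.37-fold, log2 −1.24 ± 0.27 SE, adjusted p = 0.0014), and Pdk1 (2.88-fold) fell. In the glycolysis and hypoxia list 11 of 28 measured members fell (13 adjusted over the list alone, median log2 −0.45, adjusted p = 6.9e-04, and adjusted p = 0.87 with an estimated correlation). The early growth response factor Egr2 (23-fold, log2 −4.52 ± 0.51 SE, adjusted p = 3.0e-07), Rgs16 (18.3-fold), the kinase Mast4 (at least 8.31-fold), Jsrp1 of muscle (at least 7.48-fold) and the calcium entry brake Tmem178 (at least 7.24-fold) fell. Il10 (log2 −0.10 ± 0.54 SE, adjusted p = 0.95) and Mrc1 (log2 1.23 ± 0.55 SE, adjusted p = 0.12) did not pass, and Nos2, Ido1, Il12b, Cxcl9 and Retnla were below background in both groups. With the slide as a random block 3611 genes were called.

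Binding of immunoglobulin during IFN-γ treatment was examined on shared slides. 694 genes were called (381 higher, 313 lower), 1103 with the replicate number as a block and 1338 with the slide as one, and 99.9% of the calls had the same direction on all 3 slides. Arg1 rose 8.55-fold (log2 3.10 ± 0.40 SE, adjusted p = 3.9e-05) and Pdpn, a mucin-like protein of activated macrophages, at least 36.9-fold, as did Htr2b (at least 4.59-fold) and the stefin-type protease inhibitors Cstdc4 (17.4-fold with 2 of the 3 dimmer arrays above background), Csta2 (15.8-fold, log2 3.99 ± 0.65 SE, adjusted p = 5.2e-04) and Cstdc6 (14.7-fold). Ccl7 (9.64-fold, log2 3.27 ± 0.58 SE, adjusted p = 0.0012) and Ccl2 (3.50-fold, log2 1.81 ± 0.32 SE, adjusted p = 0.0012) rose. In the chemokine list 2 of 21 measured members rose (5 and 1 fell adjusted over the list alone, median log2 0.41, 0.27 at bounds, adjusted p = 0.032, and adjusted p = 0.72 with an estimated correlation). The granulocyte genes Stfa2 (at least 1.65-fold) and Stfa2l1 (13.2-fold with 1 of the 3 dimmer arrays above background) rose too, but Mpo (adjusted p = 0.14), Ctsg (0.34) and their list (0.46) did not pass. H2-Aa fell 3.77-fold (log2 −1.91 ± 0.53 SE, adjusted p = 0.038). Of the class II list 2 of 12 measured members fell (8 adjusted over the list alone, median log2 −0.86, adjusted p = 8.2e-05, and adjusted p = 0.72 with an estimated correlation). Apoe, which carries cholesterol out of macrophages, fell 8.01-fold (log2 −3.00 ± 0.44 SE, adjusted p = 1.7e-04), and Fcgrt 3.47-fold. The natriuretic peptide receptor Npr2 (14.9-fold, log2 −3.89 ± 0.68 SE, adjusted p = 0.0010), Exoc3l2 (at least 3.32-fold), Apol7c (at least 2.47-fold), the lipid transporter Abca9 (9.66-fold with 1 of the 3 dimmer arrays above background) and Nat8l, which makes N-acetylaspartate (8.09-fold with 1 of the 3 dimmer arrays above background), fell. Mmp13, a collagenase, rose 3.65-fold (log2 1.87 ± 0.25 SE, adjusted p = 5.0e-05). Cd274 (log2 0.16 ± 0.18 SE, adjusted p = 0.78), Il10 (log2 −0.06 ± 0.54 SE, adjusted p = 0.98), Tnf (log2 0.00 ± 0.34 SE, adjusted p = 1.00) and Mrc1 (log2 −0.98 ± 0.55 SE, adjusted p = 0.42) did not pass. Cxcl9 did not pass (log2 −2.19 ± 0.70 SE, adjusted p = 0.079), with an adjusted p = 0.044 under the replicate block. Nos2 (adjusted p = 0.90) and Ido1 (adjusted p = 0.88) did not pass, and Il12b and Retnla were below background in both groups. Single arrays weighed heavily: without IFN-γ macrophage array 1 or 2 the count was 274 or 338, and without M2b array 2 or 3 it was 413 or 245. It was 275 with normexp, 425 with only these groups in the fit and 341 on a single scan day, chosen after seeing the data.

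Mreg grown from unsorted adherent cells were set against those from sorted monocytes, on shared slides. 2118 genes were called (1174 higher, 944 lower in unsorted cultures), and 98.7% had the same direction on all 3 slides. Higher were the stem cell antigen Cd34 (18.8-fold with 2 of the 3 dimmer arrays above background), the platelet chemokine Ppbp (15-fold, log2 3.90 ± 1.07 SE, adjusted p = 0.018), Slco2b1 (13.8-fold), Sgsm1 (at least 6.13-fold) and neutrophil collagenase Mmp8 (12.6-fold, log2 3.66 ± 0.59 SE, adjusted p = 2.7e-04). Pf4, stored in platelets, was 2.88-fold (log2 1.53 ± 0.41 SE, adjusted p = 0.016) higher. Among erythroid and megakaryocyte markers 4 of 15 measured members were higher (5 adjusted over the list alone, median log2 0.49, 0.40 at bounds, adjusted p = 0.033, and adjusted p = 0.62 with an estimated correlation). That list did not pass with the slide (adjusted p = 0.074) or the replicate number (0.078) as a block. Plac8 (7.04-fold, log2 2.81 ± 0.56 SE, adjusted p = 0.0016) and C1qa, the first component of complement (5.94-fold), were higher, as was Arg1 (2.84-fold, log2 1.5 ± 0.40 SE, adjusted p = 0.015). Genes of other cells were also called higher, among them Hdc (at least 2.74-fold), the mast cell protease Cma1 (at least 1.89-fold) and the IgE receptor Fcer1a (at least 3.61-fold), Stfa2 (at least 1.41-fold) and Stfa2l1 (9.01-fold with 1 of the 3 dimmer arrays above background) of granulocytes, and Il2rb of T and NK cells (at least 1.47-fold). These genes' lists did not pass (adjusted p = 0.059 for mast cells and kin, 0.071 for granulocytes, 0.12 for T and NK cells). In the glycolysis and hypoxia list 5 of 28 measured members were higher (12 adjusted over the list alone, median log2 0.50, adjusted p = 0.0041, and adjusted p = 0.62 with an estimated correlation). Tnf was 2.65-fold (log2 −1.41 ± 0.34 SE, adjusted p = 0.0079) lower. Ceacam10 (at least 2.28-fold), Zcchc14 (at least 1.61-fold), the histone methyltransferase Nsd1 (3.73-fold, log2 −1.90 ± 0.27 SE, adjusted p = 6.8e-05), Nfkbiz, a nuclear NF-κB cofactor (3.59-fold with 2 of the 3 dimmer arrays above background), and neuropeptide Npy (3.52-fold) were lower. Cd274 (log2 0.12 ± 0.18 SE, adjusted p = 0.72), Il10 (log2 0.07 ± 0.54 SE, adjusted p = 0.95), Cxcl9 (log2 1.54 ± 0.70 SE, adjusted p = 0.15), Mrc1 (log2 0.68 ± 0.55 SE, adjusted p = 0.46), Nos2 (adjusted p = 0.87) and Ido1 (adjusted p = 0.66) did not pass, and Il12b and Retnla were below background in both groups. This comparison was the least settled. The count was 911 without Mreg array 3, 902 without unsorted array 2 and 780 with normexp. The slide or replicate block gave 3777 or 3382. A limma fit on the 6 arrays alone called 0 genes, with 3104 at an unadjusted p under 0.05 and a smallest adjusted p = 0.13. With quantile normalization 42.7% rather than 55.4% of calls were higher.

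Mo-DC were compared with IFN-γ macrophages on shared slides. 8367 genes were called (3941 higher, 4426 lower in Mo-DC), and 99.2% had the same direction on all 3 slides. The retinol carrier Rbp4 was at least 22770-fold higher, Ccl17, which draws CCR4-bearing T cells, 15810-fold with 1 of the 3 dimmer arrays above background, Retnla at least 2598-fold, the eosinophil attractant Ccl24 7563-fold (log2 12.88 ± 0.77 SE, adjusted p = 2.9e-13) and the oxidized LDL receptor Olr1 at least 1267-fold. Arg1 was 649.6-fold (log2 9.34 ± 0.40 SE, adjusted p = 3.8e-16) higher and Nos2 at least 59.1-fold. Of the IL-4 list 27 of 29 measured members were higher (27 adjusted over the list alone, median log2 7.21, adjusted p = 2.8e-18, and adjusted p = 0.0013 with an estimated correlation). Fscn1, which bundles actin in dendrites, was 29.8-fold (log2 4.90 ± 0.29 SE, adjusted p = 2.8e-13) higher and the lineage factor Irf4 at least 197-fold. In the dendritic cell list 12 of 19 measured members were higher and 1 lower (12 and 2 adjusted over the list alone, median log2 2.82, adjusted p = 1.8e-06, and adjusted p = 0.070 with an estimated correlation). Lat, a T cell adaptor, was higher (49.1-fold with 2 of the 3 dimmer arrays above background). Among T cell and NK cell markers 15 of 20 measured members were higher and 2 lower (16 and 2 adjusted over the list alone, median log2 2.35, 1.08 at bounds, adjusted p = 1.5e-05, and adjusted p = 0.18 with an estimated correlation). Vwf, a clotting factor of endothelium, was 4.16-fold (log2 2.06 ± 0.26 SE, adjusted p = 3.3e-07) higher. For stromal and endothelial markers 6 of 18 measured members were higher and 1 lower (6 and 1 adjusted over the list alone, median log2 0.62, 0.16 at bounds, adjusted p = 0.046, and adjusted p = 0.26 with an estimated correlation). With the slide or the replicate number as a block this list did not pass (adjusted p = 0.053 and 0.054). Folr2, a folate receptor of resident macrophages (146-fold, log2 −7.19 ± 0.41 SE, adjusted p = 1.4e-13), Ms4a4d (at least 114-fold), Ms4a4c (142-fold, log2 −7.15 ± 0.57 SE, adjusted p = 8.2e-11), Ms4a4b (82.0-fold with 2 of the 3 dimmer arrays above background) and the prostaglandin D synthase Hpgds (83.8-fold with 2 of the 3 dimmer arrays above background) were lower. Irf7, the amplifier of interferon genes, was 34.5-fold (log2 −5.11 ± 0.45 SE, adjusted p = 4.7e-10) lower. For the type I interferon list 20 of 23 measured members were lower (23 adjusted over the list alone, median log2 −2.14, adjusted p = 1.6e-08, and adjusted p = 0.32 with an estimated correlation). Mrc1 (4.70-fold, log2 2.23 ± 0.55 SE, adjusted p = 0.0015), Ido1 (12-fold) and Il12b (at least 3.09-fold) were higher, and Il10 (at least 19.0-fold), Tnf (3.49-fold, log2 −1.80 ± 0.34 SE, adjusted p = 7.8e-05) and Cxcl9 (3.47-fold) lower. Cd274 did not pass (log2 −0.08 ± 0.18 SE, adjusted p = 0.75). GM-CSF, IL-4 and M-CSF all differed between the groups and cannot be separated.

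The step from monocyte to M0 macrophage was read on shared slides. 11164 genes were called (5319 higher, 5845 lower in macrophages), and 97.6% had the same direction on all 3 slides. Macrophage elastase Mmp12 was at least 1923-fold higher, the lysosomal glycoprotein gene Gpnmb 5786-fold (log2 12.50 ± 0.24 SE, adjusted p = 1.8e-24), Folr2 5288-fold with 1 of the 3 dimmer arrays above background, Mmp13 at least 446-fold and the kinase gene Speg at least 567-fold. Trem2, a lipid sensor, was 43.5-fold (log2 5.44 ± 0.18 SE, adjusted p = 3.2e-19) higher and Cd68, a lysosomal membrane protein gene, 9.26-fold. Of the macrophage markers 15 of 19 measured members were higher and 1 lower (15 and 1 adjusted over the list alone, median log2 3.02, adjusted p = 4.5e-06, and adjusted p = 0.17 with an estimated correlation). Lipa, the lysosomal lipase, was 22.3-fold (log2 4.48 ± 0.14 SE, adjusted p = 1.2e-19) higher. In the lysosome and phagocytosis list 26 of 30 measured members were higher (26 adjusted over the list alone, median log2 2.42, adjusted p = 3.1e-13, and adjusted p = 0.088 with an estimated correlation). Mrc1 (35.9-fold, log2 5.16 ± 0.55 SE, adjusted p = 5.1e-09), Cd274 (7.96-fold, log2 2.99 ± 0.18 SE, adjusted p = 5.3e-14), Il10 (13.6-fold with 2 of the 3 dimmer arrays above background) and Arg1 (at least 1.98-fold) were higher. Granule genes were lower in macrophages: the cathelicidin Camp (33060-fold with 1 of the 3 dimmer arrays above background), Ngp (14140-fold with 2 of the 3 dimmer arrays above background), ficolin Fcnb (at least 4106-fold), Wfdc21 (at least 2571-fold) and the peptidoglycan-binding Pglyrp1 (at least 2240-fold).

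Marker lists of other cells moved with them. S100a8, a calcium-binding protein of neutrophils, was 1213-fold (log2 −10.24 ± 0.48 SE, adjusted p = 2.6e-16) lower in macrophages than in monocytes. Among neutrophil and granulocyte precursor markers 18 of 18 measured members were lower (18 adjusted over the list alone, median log2 −8.62, adjusted p = 2.2e-08, and adjusted p = 0.088 with an estimated correlation). The proteinase Prtn3 was 337-fold (log2 −8.39 ± 0.52 SE, adjusted p = 9.4e-14) lower. Of the Ly6C-high markers 17 of 18 measured members were lower (18 adjusted over the list alone, median log2 −5.91, −5.66 at bounds, adjusted p = 6.3e-07, and adjusted p = 0.030 with an estimated correlation). Hdc, which makes histamine, was 821-fold (log2 −9.68 ± 0.39 SE, adjusted p = 1.2e-17) lower. In the mast cell, basophil and eosinophil list 1 of 17 measured members were higher and 15 lower (1 and 15 adjusted over the list alone, median log2 −6.08, adjusted p = 1.9e-06, and adjusted p = 0.090 with an estimated correlation). The haemoglobin gene Hba-a1 was 1031-fold (log2 −10.01 ± 0.30 SE, adjusted p = 3.4e-20) lower. Among erythroid and megakaryocyte markers 2 of 15 measured members were higher and 12 lower (2 and 12 adjusted over the list alone, median log2 −3.67, −2.52 at bounds, adjusted p = 0.0013, and adjusted p = 0.24 with an estimated correlation). Vpreb3 of B cell precursors was 9.85-fold (log2 −3.30 ± 0.24 SE, adjusted p = 3.8e-12) lower, with the B cell and plasma cell list, of which 2 of 12 measured members were higher and 9 lower (2 and 10 adjusted over the list alone, median log2 −1.98, −1.61 at bounds, adjusted p = 0.014, and adjusted p = 0.24 with an estimated correlation). Cdc20, an activator of mitotic exit, was 10.4-fold (log2 −3.38 ± 0.32 SE, adjusted p = 5.1e-10) lower. Cxcl9 (at least 10.6-fold), Ido1 (at least 4.18-fold) and Tnf (1.96-fold, log2 −0.97 ± 0.34 SE, adjusted p = 0.014) were lower, and Nos2, Il12b and Retnla were below background in both groups. The share of other cells among the sorted monocytes was not measured.

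**Figure D5:**
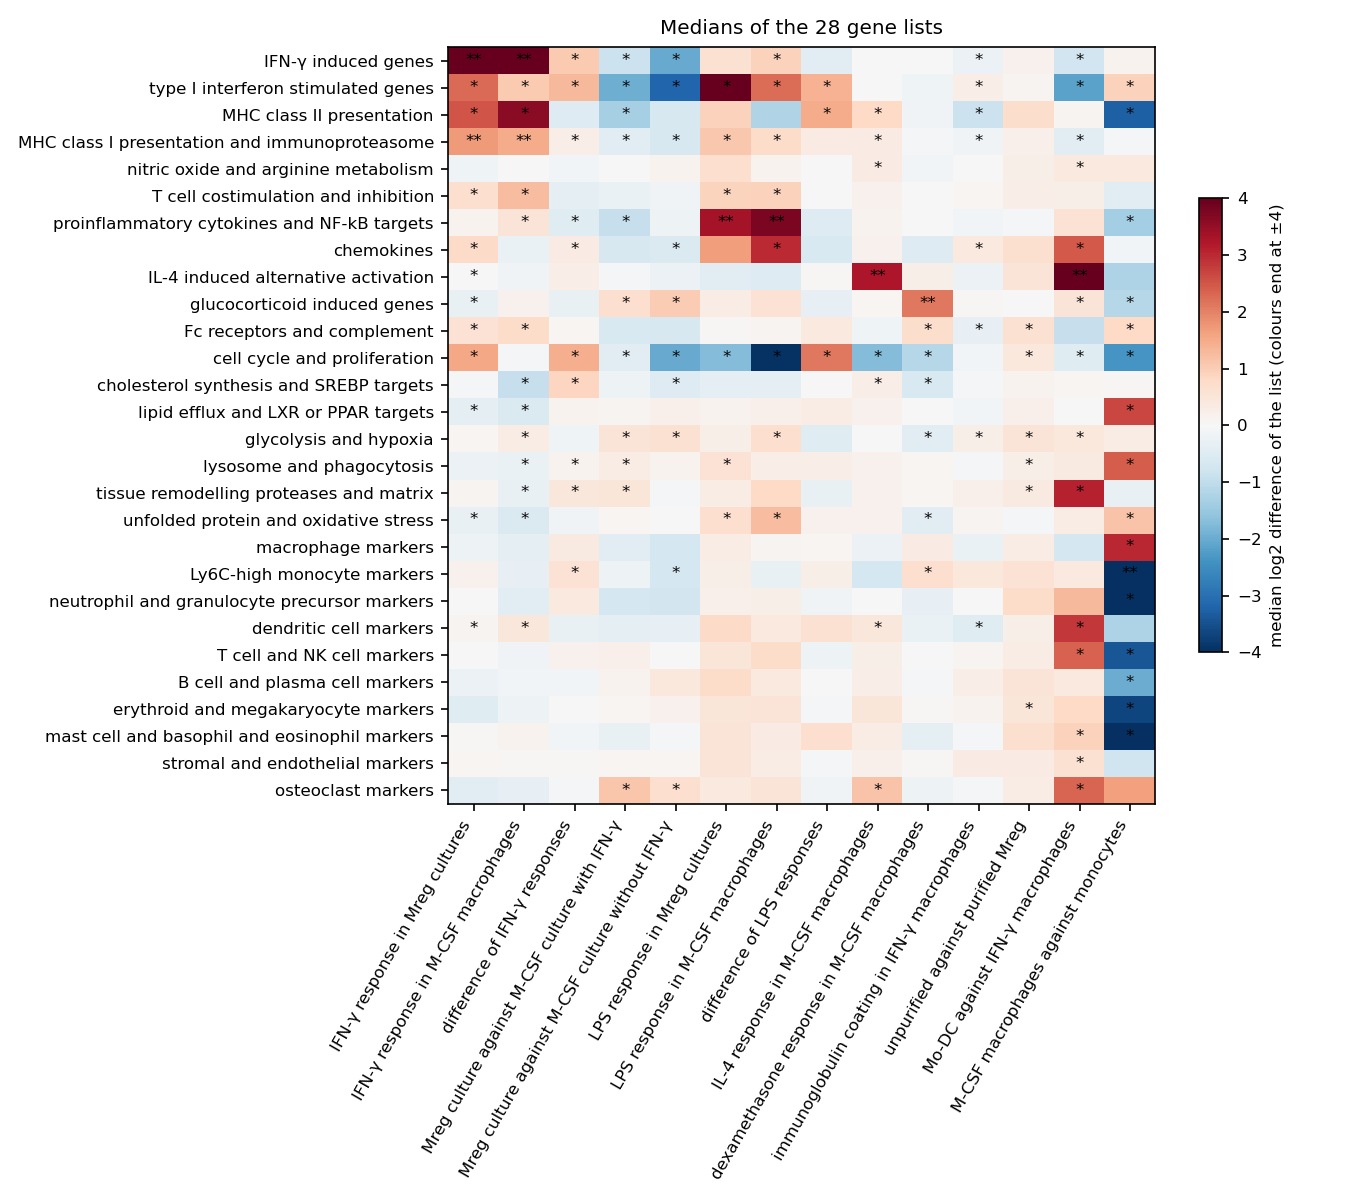
Median log2 change of 28 gene lists (vertical) in 14 comparisons (horizontal), with colours ending at 4 on either side; one asterisk marks lists past adjusted p 0.05 at the preset correlation, a pair of asterisks those also past it with an estimated one. The pairs lie in the IFN-γ, MHC class I, proinflammatory, IL-4, glucocorticoid and Ly6C-high lists.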

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

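The tests of the Nos2 probe, of the IFN-γ list in Mreg, of opposite LPS responses, of the slide block and of the marker lists in monocytes were chosen only after the result was seen; the test of dim probes and the splits of the arrays were set before the data were examined.

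Nos2 was weak in Mreg, well above background on 1 of 3 arrays, and stood at log2 −8.28 against M1. A probe blind to Nos2 is argued against by its rise of at least 376-fold with LPS in M-CSF macrophages, and a cytokine that did not act by the 27 of 28 IFN-γ-induced genes that rose in Mreg. In Mreg given LPS it read log2 1.99 against −5.43 without, near the 2.86 of M1, so the lack of LPS goes with most of that gap. IFN-γ macrophages without LPS were no higher than Mreg (log2 −6.03, on 0 of 3 arrays above background; adjusted p = 0.38). Mo-DC carried Nos2 without LPS on all 3 arrays (log2 0.19) at the same dose and time of IFN-γ, and what in their culture goes with this stays open.

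The LPS responses of the cultures differed in 6153 genes. Dim probes are argued against as the source, since 42.0% of the genes well above background on all 12 arrays passed, against 35.0% of all genes. A single response of smaller size in Mreg is argued against by 699 of 5459 measured genes called in both cultures in opposite directions. A random slide block (6600 genes) cannot decide on slides, since M1 and IFN-γ macrophages shared none. Slide, serum, M-CSF dose and cell state before LPS also stay open, tied together by the design.

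Markers of other cells fell from monocytes to M0 macrophages. If sorted cells only held fewer monocytes, every other list was predicted to move alike. The granulocyte list fell by log2 8.62 (quartiles −10.65 to −4.08) and the B cell list by 1.61 (quartiles −2.77 to −0.47), a difference of −7.00 (permutation test of genes between the lists, p = 7.3e-04). The granulocyte list was taken because it fell most, and genes of a list are not independent. Other cells may be present at unequal shares, so unequal falls cannot decide on sort purity. The other medians were −6.08 (mast cells and their kin), −2.54 (T and NK cells), −2.52 (erythroid cells) and −0.44 (stromal cells, not past the threshold), and their differences were not tested. Granulocyte precursors among the sorted cells, or granule transcripts of young monocytes, could each produce the granulocyte fall, and no test separates them. The other falls stay open.

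Differences between the cultures in the IFN-γ response that passed their own test are listed here. They were 290 genes and 10 lists: IFN-γ-induced genes (adjusted p = 1.5e-14), type I interferon genes (7.1e-14), MHC class I (3.0e-04), proinflammatory genes (0.0027), chemokines (0.019), cell cycle (2.2e-32), cholesterol synthesis (2.5e-15), lysosome (0.013), tissue remodelling (3.0e-04) and Ly6C-high markers (0.022), of which 0 passed with an estimated correlation. Named genes differed by log2 1.47 (Irf1), 4.12 (Tgtp1), 1.95 (Mcm5), 1.62 (Mcm7), 1.40 (Insig1), 5.15 (Cx3cl1), 4.68 (Ly6a), −3.43 (Ddx4) and −1.39 (Vegfa). For LPS the lists were type I interferon genes (adjusted p = 6.6e-04), MHC class II (0.020) and cell cycle (1.2e-12), and 0 of these passed with an estimated correlation. The genes were Lpar1 (−5.51), Ccl2 (−4.05), Ccl7 (−5.02), Tnf (−2.15), Nqo1 (−3.66), Txnrd1 (−2.06), Tlr4 (−2.24), Cd40 (2.23), Vsir (2.96), Sgk1 (3.91), Oasl2 (2.27) and H2-Aa (2.73).

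For 12 comparisons of 3 against 3 arrays there are only 10 splits, too few for a share under 0.05; in each, 1 split, the real one, gave the largest count. The real and the highest other counts were 3596 and 3 (IFN-γ in Mreg), 3907 and 1 (IFN-γ in M-CSF macrophages), 4929 and 1 (cultures with IFN-γ), 5439 and 3 (cultures without), 10103 and 48 (LPS in Mreg), 9013 and 0 (LPS in M-CSF macrophages), 2209 and 1 (IL-4), 3635 and 1 (dexamethasone), 694 and 5 (immunoglobulin), 2118 and 451 (unsorted cells), 8367 and 2 (Mo-DC) and 11164 and 2 (monocytes). What produced the 451 for unsorted cells was not tested. Of 100 relabellings, 1 in each case, the real one, gave the largest count for the differences of IFN-γ responses (290, highest other 0) and LPS responses (6156 in this fit, highest other 3058) and for genes higher (157, highest other 1) and lower (172, highest other 0) in Mreg. Real differences between groups enter the residual spread of the other relabellings and lower their counts, and slides were not kept together, so chance is not taken as excluded here. Nor was it excluded for the number of lists that passed, since 43 of 100 relabellings gave 137 or more (highest other 200, median 129). Relabelled groups mix cell types, and with the estimated correlation only 10 list results passed.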

How the results depend on the processing

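The fit on a single scan day was chosen only after the results were seen; the other alternatives were fixed before the data were examined. Unless a reason is given, the cause was not tested. Over all settings, list results kept their direction and side of the threshold in 2098 cases and fell short in 172; named genes kept theirs in 17122, fell short in 730, newly passed in 35 and changed sign in 110 that had not passed and in 18 that had; none of the 18 passed in the new direction (smallest adjusted p = 0.27).

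Normexp background lowered the counts to 2236 (IFN-γ in Mreg), 38 (IFN-γ difference), 3175 and 3095 (cultures with and without IFN-γ), 3872 (LPS difference), 275 (immunoglobulin) and 780 (unsorted cells), and to 92 higher and 90 lower genes in Mreg. All reversed genes came from it. Their log2 values there were −0.27 (Nos2), −0.067 (Ido1), −0.20 (Vcan) and −0.41 (Hdc) for IFN-γ in Mreg, −0.49 (Nos2), −0.36 (Ido1), −0.32 (C1s1) and −0.089 (Pecam1) for IFN-γ in M-CSF macrophages, −0.28 (Tnfsf10) for the IFN-γ difference, 0.016 (Vpreb1) for LPS in Mreg, 0.23 (Cd8a), 0.088 (Vpreb1) and 0.06 (Pdgfrb) for the LPS difference, −0.12 (Ccl22) for IL-4, −0.021 (Vsig4) and −0.28 (Retnlg) for dexamethasone, and 0.29 (Retnla) and 0.13 (Cd8a) for M0 against monocytes.

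Without a filter on dim probes 180 genes passed for the IFN-γ difference and 13875 for LPS in M-CSF macrophages, 70.7% of them higher against 54.4%. A fit of the compared groups alone raised the IFN-γ difference to 567. With fewer samples it gave 2371 (IFN-γ in Mreg), 1465 (IL-4, 43.8% higher), 425 (immunoglobulin) and 0 (unsorted cells, 3104 at an unadjusted p under 0.05). One scan day, also with fewer samples, gave 1987 (IFN-γ in Mreg), 71 (IFN-γ difference, 47.9% higher against 72.1%), 958 (IL-4) and 341 (immunoglobulin).

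The replicate block gave 470 (IFN-γ difference, 61.1% higher), 1103 (immunoglobulin) and 3382 (unsorted cells), and the slide block 1338 (immunoglobulin) and 3777 (unsorted cells). Numbers paired the arrays in 7 comparisons; the lowest pair correlations elsewhere were 0.049 and 0.068 (cultures with and without IFN-γ), 0.060 (unsorted cells), 0.079 (Mo-DC) and 0.019 (monocytes). Where they paired, the block also ended the dendritic list for IFN-γ in M-CSF macrophages (adjusted p = 0.067) and, for immunoglobulin, the IFN-γ-induced (0.059) and dendritic lists (0.062); apart from those given in the report it changed the call of no other gene or list named there, while the counts above show that many further genes changed.

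With quantile normalization calls for LPS in Mreg went from 55.7 to 45.5% higher (median of all genes from log2 0.17 to −0.02), for IL-4 from 53.8 to 43.6% and for unsorted cells from 55.4 to 42.7%; the series table gave 45.5, 43.7 and 42.9%. The median for LPS in M-CSF macrophages went from 0.12 to −0.01 and for M0 against monocytes from −0.08 to 0.07. Normexp gave medians of −0.21 (IFN-γ in both cultures), 0.36 (LPS in Mreg), 0.16 (LPS difference), −0.15 (IL-4), −0.20 (dexamethasone), 0.15 (Mo-DC) and 0.18 (monocytes), and 45.5% of calls higher for unsorted cells.

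Leaving out 1 array at a time gave 2378 to 3574 (IFN-γ in Mreg), 3077 to 3374 (in M-CSF macrophages), 124 to 228 (IFN-γ difference), 3663 to 4587 and 4262 to 4853 (cultures), 9141 to 9812 and 8008 to 8392 (LPS), 5581 to 6116 (LPS difference), 1309 to 2151 (IL-4), 2696 to 3065 (dexamethasone), 245 to 664 (immunoglobulin), 902 to 2241 (unsorted cells), 7437 to 7737 (Mo-DC), 10469 to 10803 (monocytes), 119 to 163 and 139 to 178 (higher and lower in Mreg) and 128 to 141 lists. Passing lists numbered 128 to 161 under the other settings. The difference of Nos2 between Mreg and M1 was −5.62 with normexp, −8.06 with quantile normalization, −7.99 in the series table and −8.56 to −8.05 with arrays left out; the filter of 18 arrays removed its probe and gave no value. Signal over background limits the rest.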
